A study of Mus musculus with 2 samples.

How the data were processed

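Total RNA of uterine stromal cells of floxed control and Hand2-null mice was pooled by genotype and hybridized to 1 Affymetrix mouse array for each, per the labels' protocols and the series design. Per the labels' protocols, epithelial clumps were loosened with dispase and pancreatin and discarded, the remaining tissue was digested with collagenase and filtered, and the cells were left to attach to plates before the unattached ones were removed. The labels state 100 ng of RNA for labelling with the Affymetrix 3' Express kit. Both arrays name the same mixed C57BL/6 and SV129 background, with the PRcre line listed for each. The number of mice is given as 5 per genotype in the series design and 4 in the extraction protocol, and the values do not settle it.

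The deposited values are linear array intensity (MAS5 signal), made by the authors with MAS5 in Affymetrix Expression Console version 1, per the submitters' processing notes. The mean signal after trimming 2% at each end was 150.001 in both arrays, which shows that each array was scaled to the same mean before deposit. Normalization between arrays beyond this scaling is not given in the sources used here, nor is a genome build, so no coordinates are printed. Detection calls were not used here. Scaling to a common mean assumes that most transcripts do not differ, and MAS5 subtracts mismatch probes, which makes ratios of dim probe sets unsteady.

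Of 45101 probe sets, 64 controls were left out of the comparison, 34945 of the others had 1 gene in the platform annotation, 932 had several and 9160 had none listed. Of 34958 annotation entries with 1 gene, 34754 matched a RefSeq gene of the GRCm38.p6 annotation by Entrez ID, and 0 symbols changed by the match. That table was used for names and for which genes neighbour each other. Signals were put on a log2 scale. The floor of each array was its 60th percentile of non-control probe sets, values under it were set to it, and a gene was measured when its signal reached the floor in at least 1 array. The probe set with the highest mean log2 signal stood for its gene. A difference was counted when the floored log2 ratio was at least 1 in size, and where 1 array was under the floor the fold is written as at least that value.

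Before the data were examined, the design, the alternatives, 34 gene lists with 1040 entries and the rule for named genes were fixed. Of the entries 960 matched a gene on the array. When the values of list members were first looked at, a few entries had been matched through synonyms to the wrong gene, and the matching was then limited to entries that are not themselves a RefSeq symbol. Each list with at least 5 measured genes was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean signal in 20 bins. A list was said to stand apart under the 2.5th or over the 97.5th percentile. No test was made, since 1 array per group gives no replicate error. The disagreement between probe sets of a gene and the range of all ratios stand in for it. The first does not include variation between mice, and the second cannot separate it from the difference between genotypes.

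The named genes were Hand2 and 16 genes of uterine biology fixed in advance, the 12 genes with the highest and the 12 with the lowest ratio above the floor in both arrays, the 5 brightest per direction with the other array under the floor, and up to 4 members of each list with the largest ratio in size. Genes with a measured probe set of opposite sign were left out where the rule ranks genes over the whole array. Genes named outside this rule are marked as such where they appear.

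Alternatives were centring on the median, quantile normalization, loess with a span of 0.3, floors at the 50th and 75th percentiles and none, a pseudo-signal equal to the floor, the mean over probe sets, leaving out probe sets that can cross-hybridize, thresholds of 1.5-fold and 3-fold, 10 bins, and the mean of a list in place of its median. The procedure was tested on simulated arrays with 200 genes altered, over 10359 measured genes for the comparison of Hand2-null with control. The rule called 6% of genes altered 1.5-fold, 46% of those altered 2-fold, 86% of those altered 3-fold and 86% of those altered 4-fold, and 30 of 10163 unaltered genes. Simulated lists of 30 genes were called in 3 of 100 cases with no shift and in 100 of 100 with a log2 shift of 0.3. Noise was drawn separately for each probe set and the lists were random genes. The simulation thus held no co-regulated genes and no differences in cell types or mice. Its rates of calls are therefore not error rates for the real genes and lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.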

Results

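Uterine stromal cells were isolated from mice on day 4 of pregnancy and their transcripts were measured on 2 oligonucleotide arrays, 1 for each genotype. The control array carried RNA of mice with floxed Hand2, the gene of a basic helix-loop-helix transcription factor of the uterine stroma. The other array carried RNA of Hand2-null mice, in which the floxed gene was crossed with PRcre, a line that makes Cre recombinase from the progesterone receptor locus. RNA was pooled over mice before hybridization, so there was no replicate, no p-value and no error of a difference, and every value below compares these 2 pools. The series design gives 5 mice per genotype, whereas the extraction protocol in the labels gives 4.

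Each array held 45101 probe sets, and 10376 of the 18193 named genes had a signal at or above the floor in at least 1 array. The median signal was 35.1 in the control array and 36.4 in the Hand2-null array, with floors of 64.2 and 67.5. Log2 signals of the 17111 probe sets above the floor in both arrays had a Pearson r of 0.970 and a Spearman rho of 0.954, taken across probe sets, which are not independent replicates. The ratio of the 3' to the 5' control probe set was 1.00 and 1.05 for Gapdh and 1.76 and 1.499 for Actb, control array first. Spiked bioB, bioC and bioD transcripts differed between the arrays by log2 ratios of -0.08 to 0.10, and the 24 control probe sets of dap, lys, phe and thr by -0.28 to 0.34, with a median of -0.02. In place of a replicate error, different probe sets of the same gene had a standard deviation of 0.18 in log2 ratio over 3665 genes, from 0.23 in the dimmest quartile of genes to 0.13 in the brightest. The middle 95% of all measured genes had log2 ratios between -0.66 and 0.93, where a positive ratio means a higher signal in the Hand2-null array. The number of arrays limits the precision of every value.

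Hand2 was the first gene read, because it checks the labels. Its bright probe set, 1436041_at, had a signal of 1545 in the control array and 38.5, under the floor, in the Hand2-null array, which is at least 22.9-fold lower. Its other probe sets, 1422221_at and 1443854_at, were under the floor in both arrays, at 37.1 and 18.1 in the control and 8.04 and 2.46 in the Hand2-null array. The labels do not state which exons the floxed allele removes, so the position of these probe sets relative to the deletion is not known here.

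The main comparison asked which transcripts of the stromal cell isolates differed when Hand2 was ablated. The isolates also held epithelial and smooth muscle transcripts, and the smooth muscle markers were higher in the Hand2-null array with a median log2 ratio of 1.36. The cell type that held each transcript is therefore not known here. Slc6a2, the noradrenaline transporter, had a signal of 2054 in the control array and was at least 30.4-fold lower in the Hand2-null array, although its dimmest measured probe set, near the floor in the control and under it in the Hand2-null array, showed a log2 ratio of -0.08. Spink1, a trypsin inhibitor, went from 1686 in the control to under the floor and was at least 25.0-fold lower, and Cyp1b1, a cytochrome P450 that hydroxylates estrogens, was at least 7.81-fold lower by its bright probe set and showed a log2 ratio of -0.05 by a probe set near the floor. Among genes above the floor in both arrays, S100g, a calcium-binding protein, had signals of 3112 and 625, or 4.98-fold lower, and Ttr, the carrier of thyroid hormone, was 4.93-fold lower. The higher genes were led by Prap1, a secreted proline-rich protein, at 101 against 762 or 7.54-fold higher, Myom1, a protein of the sarcomere, at 7.15-fold higher, and Inhbb, the activin beta-B subunit, at 6.09-fold higher. The value of Myom1 rests on 1 probe set with a control signal of 76.5, near the control floor of 64.2.

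**Figure D1:**
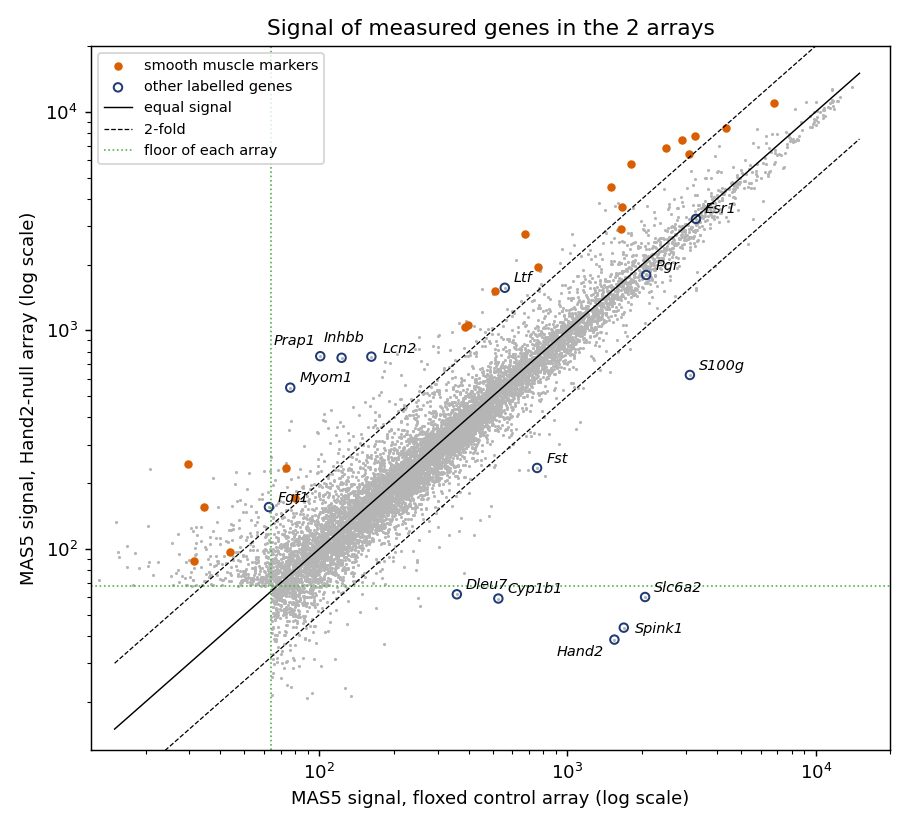
MAS5 signal of each measured gene in the floxed control array (horizontal, log scale) and the Hand2-null array (vertical, log scale), 1 point per gene, with smooth muscle markers in orange. Hand2, Slc6a2 and Spink1 lie far below the 2-fold line, at 38.5, 60.3 and 43.7 in the Hand2-null array, while Pgr and Esr1 lie near the line of equal signal.

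In all, 206 genes, or 1.99% of those measured, had a signal at least 2-fold higher in the Hand2-null array and 77, or 0.742%, at least 2-fold lower. Of these, 36 and 11 had the other array under the floor, so that their folds are bounds. Among genes with several measured probe sets, 0 of the 66 higher genes and 1 of the 22 lower genes had a probe set of the opposite sign. Further lower genes were Vit, a matrix protein, at 3.77-fold, Angptl7 at 3.64-fold, Jazf1 at 3.44-fold, Tmem87a at 3.27-fold, Fst, the activin-binding follistatin, at 3.21-fold with signals of 754 and 235, Car12, a carbonic anhydrase, at 3.14-fold, Map2, Ctse and Cdh10 each at 3.06-fold, and the imprinted Mest at 3.02-fold. Dleu7 was at least 5.31-fold lower. Further higher genes were Hspb7, a small heat-shock protein of muscle, at 5.00-fold, Lcn2, a secreted lipocalin, at 4.67-fold, the cytokine Il17a at 4.66-fold on a single probe set, and Cnn1, the smooth muscle calponin, at 4.06-fold with signals of 676 and 2747. Control signals of Hspb7 and Il17a, at 77.3 and 75.5, were near the floor. Agtr2, an angiotensin receptor, was 3.96-fold higher, the matrix proteoglycan Prelp 3.91-fold, Jph2 of muscle membrane junctions 3.87-fold, Sh3bgr 3.78-fold and Aspn, another small matrix proteoglycan, 3.77-fold. Slit2, a guidance ligand, was at least 4.08-fold higher, the oxytocin receptor Oxtr at least 3.81-fold, Spink12 at least 3.63-fold, Zfpm2, a cofactor of GATA factors, at least 3.54-fold and Syndig1 at least 3.52-fold. The measured probe sets of Ttr, Map2 and Cdh10 with the smallest difference showed log2 ratios of -0.81, -0.81 and -0.30, and the dimmer probe sets of Inhbb, Hspb7 and Zfpm2 showed the same sign with smaller log2 ratios of 0.39, 0.62 and 0.39. The counts depend on the floor: with it at the 75th percentile 117 genes were higher and 45 lower, and with no floor 1646 and 1626.

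The labels name fibroblast growth factors (FGFs), ligands that signal from stroma to epithelium, as a subject of the study. Of the 22 FGF ligand genes on the array, with 41 probe sets, 2 probe sets reached the floor. Fgf1 had signals of 62.8 and 155 and was at least 2.42-fold higher in the Hand2-null array, and Fgf7 had signals of 52.9 and 68.7, the second barely above the floor. Fgf2, at 1.82 and 6.13, Fgf10, at 21.2 and 24.6, Fgf18, at 7.99 and 13.5, and both probe sets of Fgf9, at 24.7 and 37.8 and at 16.7 and 31.9, were under the floor in both arrays, so no fold is given. With no floor, 14 of the 22 ligand genes were higher, with a median log2 ratio of 0.37 at the 93.5th percentile. That place lay inside the middle 95% of random lists and rests on signals mostly under the floor. Of 11 measured FGF receptors and co-receptors 7 were higher and 4 lower, with a median log2 ratio of 0.06 at the 86.7th percentile. Fgfr1 was higher by a log2 ratio of 1.13, although its second probe set showed 0.09, Fgfr2 by 0.81, with a second at 0.35, and the glypicans Gpc3 and Gpc1 were lower, at -0.86 and -0.65. Of 14 feedback and response genes of the ERK kinases, which act downstream of FGF receptors, 11 were higher, with a median of 0.21 at the 99.6th percentile. The phosphatase Dusp5 was at 1.14 and the feedback inhibitors Spry2 and Spry1 at 0.69 and 0.64, while Myc was at -0.71. By the mean in place of the median that list lay at the 97.4th percentile. Immediate-early and heat-shock genes, which respond to cell handling, were higher beside it with a median of 0.41, as were smooth muscle markers with 1.36 and mesothelial markers with 0.53.

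Pgr, the progesterone receptor, had signals of 2076 and 1791, a log2 ratio of -0.21, with its second probe set lower too and its dimmest probe set higher. Esr1, the estrogen receptor, had 3292 and 3235, a log2 ratio of -0.03, and its second probe set showed 0.42. Of 23 genes known to respond to estrogen in the uterus, 17 were higher and 6 lower, 6 were at least 2-fold higher and 0 at least 2-fold lower, and the median of 0.24 lay above all 10000 random lists. The 6 were Inhbb, Lcn2, Greb1 at 2.83-fold, Ltf, the secreted lactotransferrin, at a log2 ratio of 1.49 with signals of 559 and 1566, Clca1 at no less than 1.27 and the cell cycle inhibitor Cdkn1a at 1.06. Clca1 and Cdkn1a lie outside the rule for named genes and were named after their values were seen, to complete the 6. Muc1, a mucin of the epithelial surface, had signals of 173 and 190. Beside these, 39 epithelial markers had a median log2 ratio of 0.04 at the 91.3rd percentile, or 0.14 at the 99.8th with the floor at the 75th percentile, and Lcn2 and Ltf are on that list too. Smooth muscle markers, with a median of 1.36, mesothelial markers, with 0.53, and immediate-early and heat-shock genes, with 0.41, were higher in the same array.

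The 28 measured genes of progesterone response did not stand apart. In this list 13 were higher and 15 lower, with a median of -0.11 at percentile 9.03 of random lists, but at percentile 71.94, with a median of -0.01, with the floor at the 50th percentile. Fst and the transcription factor Klf15, at -1.15, were lower, Sgk1, a kinase, was higher at 1.20, and Bmp2, the morphogen of decidualization, was higher at 0.96 with signals of 262 and 510. Hoxa10 had signals of 1944 and 1502, a log2 ratio of -0.37, and Hoxa11 771 and 481, a ratio of -0.68. Nr2f2, the orphan receptor COUP-TFII, was at -0.31 and lower by all 5 measured probe sets, and Ihh, the hedgehog ligand made by the epithelium, was at 0.29. Of 13 hedgehog pathway genes 8 were lower, with a median of -0.08 at the 26.9th percentile. Ptch1 and Gli1, direct targets of hedgehog signalling, were at -0.85 and -0.67, against Cdon at 0.79. A second probe set of Ptch1 showed -0.33.

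Several signalling lists had medians above those of matched random lists. Of 28 genes of the BMP and TGF-beta pathway 20 were higher, with a median of 0.32 above all random lists. Inhbb, the inhibitory factor Id4, at 1.70, and Bmp4, at 1.07, were higher, and Fst was lower. The list of HAND2 partners and related factors held 13 higher and 7 lower genes of 20, with a median of 0.25 at the 99.97th percentile. It included Gata6 at 1.51 and Tcf21 at 0.93 as well as Hand2 itself, and by the mean it lay at the 80.5th percentile. Decidualization genes, 15 of 23 higher, had a median of 0.17 at the 99.9th percentile and by the mean the 81st. Of them 0 were at least 2-fold higher and 1 was at least 2-fold lower. In the Wnt list 18 of 30 genes were higher, with a median of 0.09 at the 97.9th percentile, or the 91.7th with the floor at the 75th percentile, led by Rspo3 at 1.35, Nkd1 at 1.19 and Rspo1 at 1.07 against the antagonist Sfrp2 at -1.56. Wnt4 had signals of 119 and 175. The list of EGF and IGF family ligands, which also holds other growth factors, had a median of 0.08 at the 98.0th percentile and 14 of 26 genes higher. Its 2 genes at least 2-fold lower belong to other growth factor families. They were Hgf at -1.48, with a second probe set at 0.02, and Pdgfd at -1.04, with a second at -0.30. The list lost its place outside random lists under several settings. In the list of Hox genes and their cofactors 10 of 13 genes were lower, with a median of -0.24 at the 0.58th percentile, or the 15.6th with no floor. The 3 higher genes were the cofactors Meis1, Meis2 and Pbx3, at 0.92, 0.87 and 0.62. Beside the higher lists stood the smooth muscle markers, with a median of 1.36, the mesothelial markers, with 0.53, which share Rspo1 with the Wnt list, and the immediate-early and heat-shock genes, with 0.41.

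Matrix genes were higher as a group. Of 57 structural genes of the extracellular matrix 42 were higher, 8 of them at least 2-fold, with a median of 0.34 above all random lists. Of the lower genes 1 was at least 2-fold lower. With a pseudo-signal 3 were at least 2-fold higher and 0 at least 2-fold lower. Prelp, Aspn, Ogn at 1.40 and Thbs2 at no less than 1.39 led them. Of 22 matrix proteases and inhibitors 17 were higher, with a median of 0.37 above all random lists, led by Mmp11 at 1.83 and Mmp3 at 1.60, with Lox at 0.88. The smooth muscle median of 1.36, the mesothelial median of 0.53 and the immediate-early and heat-shock median of 0.41 went the same way as these lists. Prostaglandin genes had a median of 0.01 at the 68.9th percentile, with Ptgis, the prostacyclin synthase, at 1.56 and Ptger4, a receptor of prostaglandin E, at -0.93. Retinoid genes had a median of 0.11 at the 93.9th percentile, with Aldh1a1 at 0.93 against Stra6 at -0.82 and Aldh1a2 at -0.71.

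Cell cycle genes were lower almost throughout. Of 44 measured genes 41 were lower and 3 higher, none by 2-fold, and the median of -0.28 lay below all random lists. Ube2c was at -0.82, Ccnb2 at -0.54, Cdk1 at -0.53 and Nek2 at -0.80 or lower, its Hand2-null signal being under the floor. Beside this list the smooth muscle markers had a median of 1.36. Ribosomal protein genes, 31 of 32 lower, had a median of -0.14 at the 0.57th percentile, but after quantile normalization they lay at the 24.28th percentile. Rpl14 was at -0.69 and Rps6 at -0.42. Oxidative phosphorylation genes had a median of -0.06 at the 40.8th percentile, or 0.01 after loess, with Atp5o at -0.35. Immediate-early and heat-shock genes, which respond to cell handling, were higher in 29 of 34, with a median of 0.41 above all random lists, and Fosb, Atf3 and Nr4a2 were at 0.98, 0.88 and 0.83.

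**Figure D2:**
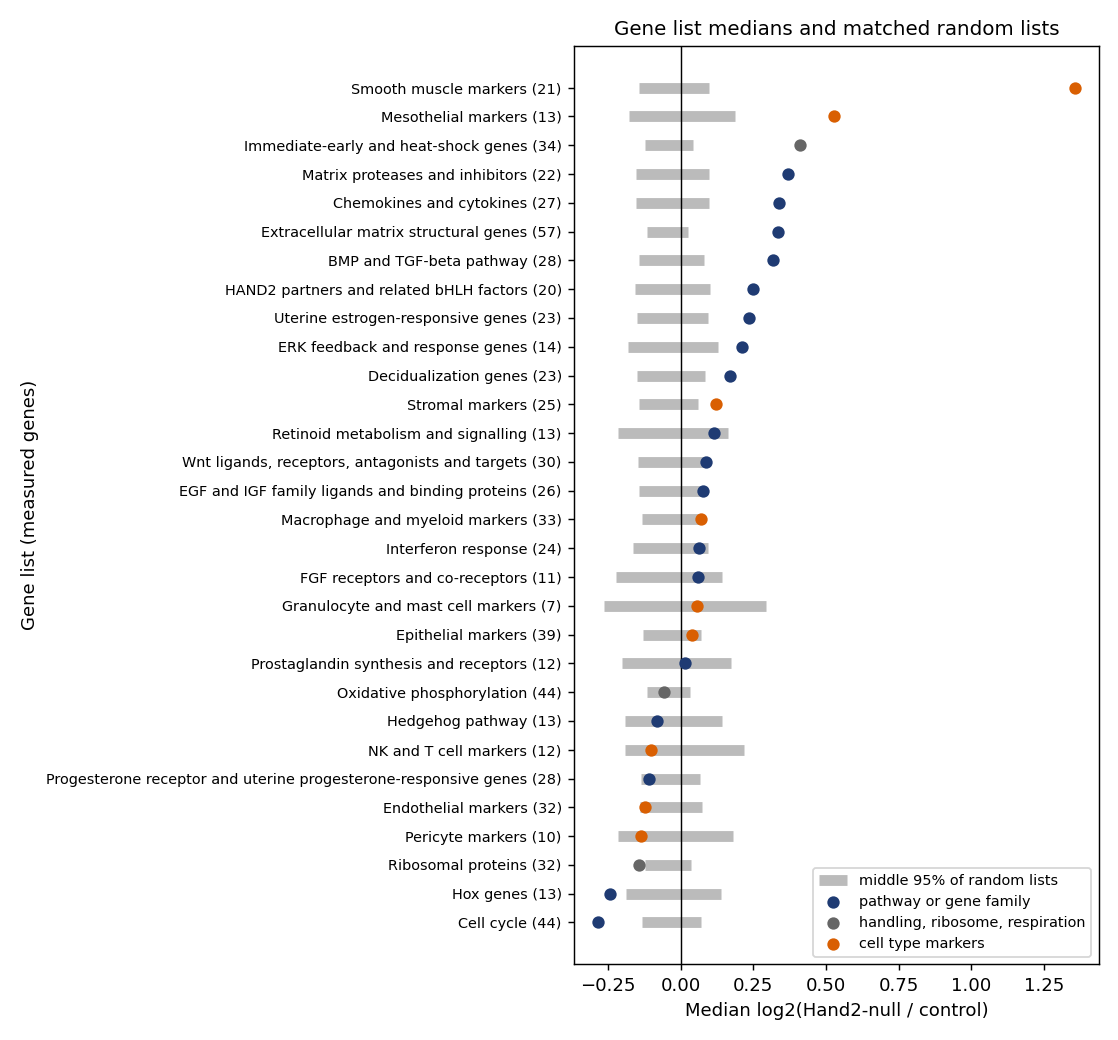
Median log2 ratio, Hand2-null over control, of each gene list (horizontal), with 1 point per list and the number of measured genes in brackets, and grey bars for the middle 95% of 10000 random lists matched on mean signal. The smooth muscle list lies at 1.36 and the cell cycle list at -0.28, both outside their grey bars.

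Immune genes were mixed. Of 27 chemokines and cytokines 22 were higher, with a median of 0.34 above all random lists, among them Cxcl16 at 1.12, Cxcl10 at 0.91 and Cxcl1 at 0.90. The medians of immediate-early and heat-shock genes, 0.41, of smooth muscle markers, 1.36, and of mesothelial markers, 0.53, lay on the same side. Interferon response genes had a median of 0.06 at the 93.5th percentile, with Ifit3 at 0.82 and Irf1 at 0.73. Macrophage and myeloid markers had a median of 0.07 at the 98.1st percentile and by the mean the 88.7th, with Clec10a at 1.19 against Cx3cr1 at -0.63. Natural killer and T cell markers had a median of -0.10 at the 11.8th percentile, with Cd3g at 0.89 against Klra8 at -0.74 and the granzymes Gzma and Gzmb at -0.47 and -0.45. Among 7 granulocyte and mast cell markers the median was 0.06 at the 68.3rd percentile, and the mast cell proteases Cpa3 and Cma1 were higher at 1.65 and 1.37 while S100a9 of neutrophils was lower at -0.98. The direction of this list turned with the setting: its median was -0.56 before flooring over the same genes, 1.12 at percentile 100 with no floor over all its genes, and -0.38 at percentile 0.03 with a pseudo-signal.

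Markers of other cell types in the uterine wall were read with the same rule. Of 21 measured smooth muscle markers 21 were higher, 16 of them at least 2-fold, with a median of 1.36 above all random lists. Cnn1, Myh11, the smooth muscle myosin heavy chain, at 3.21-fold with signals of 1795 and 5768, Lmod1 at 3.17-fold and Oxtr led them, and 17 of the 21 were at or above the floor in the control array too. Mesothelial markers, of the cell layer on the outer face of the uterus, were higher in 11 of 13, with a median of 0.53 above all random lists, led by Gpm6a at 1.77, with a second probe set at 0.56, Upk3b at 1.42 and Rspo1, with 7 of the 13 above the floor in the control array. In the smooth muscle and mesothelial lists the remaining genes were measured through the Hand2-null array alone. Under the floor rule those genes could only come out higher. With the floor at the 50th percentile the mesothelial median was 1.12 and 9 genes were at least 2-fold higher, against 3 here. Stromal markers, 15 of 25 higher, had a median of 0.12 at the 99.7th percentile and by the mean the 89.5th, with Fbln1 at 1.08 and Col1a1 at 0.98 against Nt5e at -1.53. Epithelial markers were split between 20 higher and 19 lower, among them Spink1 and Cldn10 at -0.99 on the lower side, and their median before flooring was -0.01. Endothelial markers had a median of -0.12 at the 5.28th percentile but a mean of 0.01, with Cldn5 at 1.55, Lyve1 at 1.54 and Mmrn1 at 1.40 against Cdh5 at -1.11. Pericyte markers had a median of -0.14 at the 13.6th percentile, with Cspg4 at 0.79 against Rgs5 at -0.48. B cell, erythroid and nerve or Schwann cell markers had 3, 2 and 4 measured genes, too few for a percentile. Of these, Mzb1 was at -0.81, Hbb-b2 at -0.28 or lower, its Hand2-null signal being under the floor, and Ncam1 at 0.94.

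**Figure D3:**
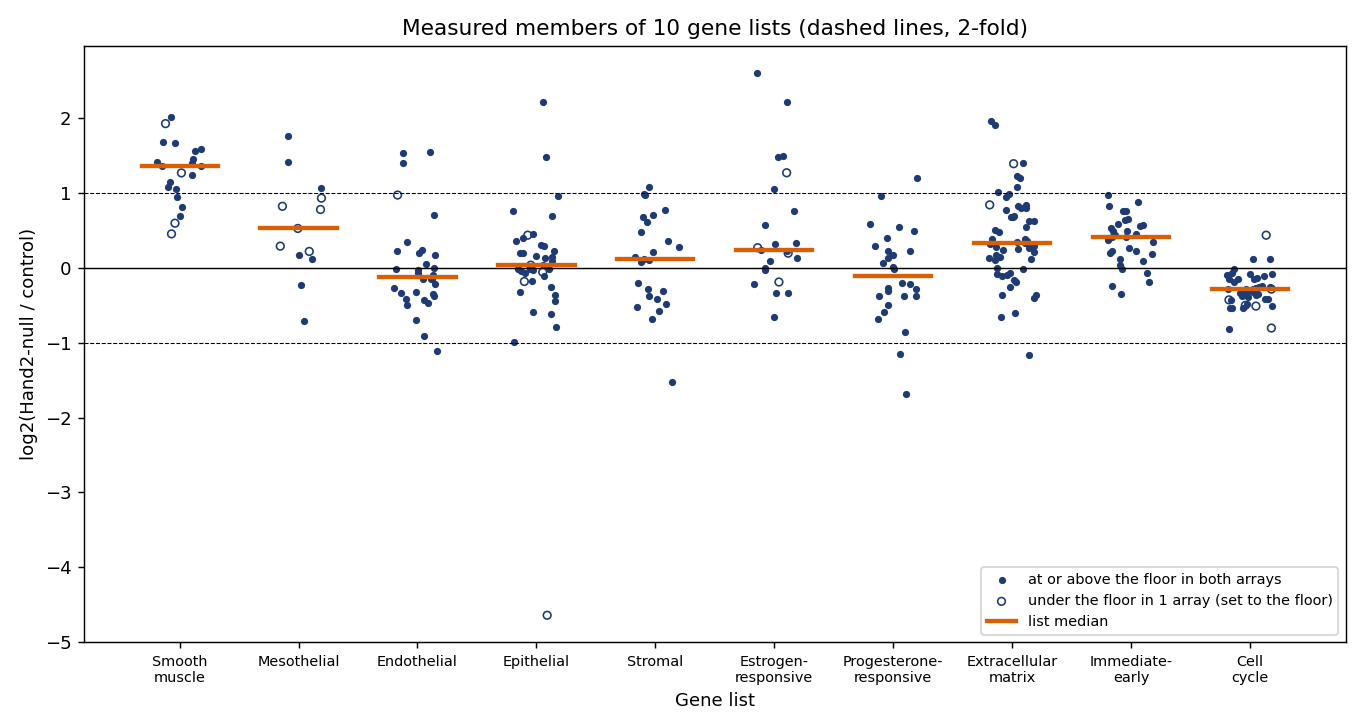
Log2 ratio, Hand2-null over control (vertical), of each measured member of 10 gene lists, with open points for genes under the floor in 1 array, an orange bar at each list's median and dashed lines at 2-fold. All 21 smooth muscle markers lie above 0 and 41 of 44 cell cycle genes below it, while epithelial markers spread to both sides.

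Of the 34 lists, 15 had medians above and 3 below the middle 95% of random lists, 12 lay inside it and 4 had too few measured genes. The percentiles describe these 2 arrays and treat genes as independent, which co-regulated genes are not. The lists also share members, among them 12 of 23 decidualization, 9 of 23 estrogen-responsive, 13 of 25 stromal and 8 of 28 BMP and TGF-beta genes found on another list, so the calls are not separate.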

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

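Probe sets that are not paired with exactly 1 gene took no part in the comparison of genes, and a signal also appeared there. Of 10092 such probe sets 2216 were measured, 57 of them at least 2-fold higher in the Hand2-null array than in the control array and 9 at least 2-fold lower. Above the floor in both arrays, 1444693_at was 5.02-fold and 1443983_at 3.97-fold higher, and 1455038_at was 3.54-fold and 1428720_s_at 2.83-fold lower. Their genes were not analysed here.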

How the results depend on the processing

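All alternatives here were chosen before the data were examined. No paired analysis was possible because each genotype has 1 pooled array, and for the same reason no replicate could be left out. Counts of genes at least 2-fold higher and lower stayed within 1.5 times of 206 and 77 under centring, quantile normalization, loess, the floor at the 50th percentile, the mean over probe sets and without cross-hybridizing probe sets. They were 117 and 45 with the floor at the 75th percentile, 1646 and 1626 with no floor, 117 and 40 with a pseudo-signal, 644 and 345 at 1.5-fold and 49 and 20 at 3-fold. With no floor 18193 genes were counted in place of 10376, and a threshold or pseudo-signal alters counts by its construction. The log2 ratio of Hand2 was -5.33 with the floor at the 50th percentile and with no floor, -3.23 with it at the 75th and -3.93 with a pseudo-signal, against -4.52.

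Centring on the median moves all log2 ratios by the same amount, so no list's percentile could alter under it. Of 18 lists that stood apart 9 did so under every alternative run: smooth muscle, mesothelial, extracellular matrix, matrix proteases, BMP and TGF-beta, chemokines, immediate-early, estrogen-responsive and cell cycle. For the others the cause was not tested. Ribosomal proteins lay at the 24.28th percentile after quantile normalization. The list of EGF and IGF ligands and other growth factors lay at 71.7 with the floor at the 50th percentile, 96.9 at the 75th, 53.95 with no floor, 96.2 without cross-hybridizing probe sets and 69.25 by the mean. The Wnt list lay at 91.7 with the floor at the 75th percentile and 97.47 without cross-hybridizing probe sets. The list of Hox genes and their cofactors lay at 15.6 with no floor, 3.26 by the mean over probe sets and 22.5 by the list mean. Macrophage markers lay at 96.6 with the floor at the 75th percentile and 88.7 by the mean. By the mean, ERK genes lay at 97.4, decidualization genes at 81, HAND2 partners at 80.5 and stromal markers at 89.5. The list of HAND2 partners holds the ablated Hand2 itself, at -4.52, which lowers its mean more than its median. Epithelial markers stood apart at 99.8 with the floor at the 75th percentile. Granulocyte and mast cell markers stood apart at 100 with no floor and, on the opposite side, at 0.03 with a pseudo-signal. With the floor at the 75th percentile that list and the natural killer and T cell list had too few genes for a value. Among lists that did not stand apart, these crossed to the other side of the middle of random lists without standing apart there: progesterone genes, at 71.94 with the floor at the 50th percentile and 69.35 with none, interferon genes, at 49.93 with it at the 75th, pericyte markers, at 50.495 with it at the 75th and 50.82 by the mean, endothelial and hedgehog genes, at 61.49 and 50.72 by the mean, epithelial markers, at 46.53 by the mean, and granulocyte markers, at 48.555 after loess. Mesothelial markers kept percentile 100 with no floor while their median was 1.12 in place of 0.53. Of values of named genes under alternatives, 1201 moved by less than the spread between probe sets of a gene, 164 by more, and 0 of the genes at least 2-fold different changed sign. Signal over background limits the dim genes, FGF ligands and mesothelial markers among them.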

Other observations

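The other normalizations were chosen before the data were examined, as were the tests of neighbouring genes. The epithelial panel, the mesothelial test and the counts of genes kept under the other normalizations were chosen after the results they bear on were seen.

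Some members of the endothelial and epithelial lists are given here as single values, with no claim for a group. They lie partly outside the rule for named genes and were picked after their values were seen, as were Krt19 and Acta2 in the paragraphs on estrogen-responsive and muscle genes. In the endothelial list, which did not stand apart, Prox1 had a log2 ratio of no less than 0.97 and Flt4 of 0.70, while Aplnr had -0.91 and Icam2 -0.70. In the epithelial list Foxa2 had signals of 124 and 71.9, a ratio of -0.79, and Cxcl15 a ratio of -0.62. Epithelial transcripts were present in both isolates, with Krt8 at 1704 and 1753, Cdh1 at 746 and 856 and Epcam at 714 and 800, control array first.

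The 6 estrogen-responsive genes that were at least 2-fold higher had log2 ratios of 1.06 or more and a median of 1.49, beside medians of 1.36 for smooth muscle, 0.53 for mesothelial and 0.41 for immediate-early and heat-shock genes. If epithelial cells left in the Hand2-null isolate alone brought them, a panel of 15 genes found in all epithelia would be higher by at least 1. The panel's median was 0.04, and 0.37 with 1 standard deviation of 0.33 added, with the highest member, Krt19, at 0.96. The wider epithelial list stood apart with the floor at the 75th percentile at a median of 0.14. The 6 genes were picked for being at least 2-fold higher, and the panel was not. The median of the whole estrogen-responsive list, 0.24, lay above the panel's median of 0.04 but within 1 standard deviation of it, under 0.37. The panel therefore does not decide whether epithelial cells added a smaller part. The 6 genes stayed at least 2-fold higher under each of the 3 other normalizations, so their difference does not hang on the choice among these. Because centring raised every log2 ratio equally, only quantile normalization and loess could have lowered their ratios. All 3 start from the authors' scaled signals and also assume that most transcripts do not differ, so that assumption was not tested. An effect of the genotype was not tested and stays open. So do a smaller epithelial part, the cell type that held these transcripts, the handling of the cells and added outer-wall cells.

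All 21 measured smooth muscle markers were higher, and Acta2, the most abundant, had signals of 6764 and 10979. At least 16 markers were 2-fold or more higher under each of the 3 other normalizations, so the pattern does not hang on the choice among these. Centring raised every log2 ratio equally, so of the 3 only quantile normalization and loess could have lowered this count. The assumption shared by all 3, that most transcripts do not differ, was not tested. More muscle and outer-wall cells in the Hand2-null isolate could account for the pattern, and would bring mesothelial transcripts too: that list lay at percentile 100, with a median of 0.53 or, with the floor at the 50th percentile, 1.12. However, 6 of its 13 genes were under the floor in the control array and could only come out higher, and 2 are on another list. The percentile of 100 had been seen before the test was set. Other lists, the extracellular matrix among them, lay as high, so added cells remain a hypothesis. A muscle programme in stromal cells without Hand2 also stays open, because a list median of 1.36 does not say in which cells the transcripts lay.

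Strain variants linked to the engineered alleles may alter genes near Pgr, where Cre sits, or near Hand2, but the labels list PRcre for both arrays, and if the control mice carried it too the Pgr window does not test the Cre allele. Among 9761 windows of 30 measured neighbours the median size of the log2 ratio was 0.18, with a standard deviation of 0.05. The window of Pgr had 0.15, at the 19.3rd percentile, and that of Hand2 0.21, at the 73.8th percentile. The Pgr window met the bound set in advance against linked variants, being below the median of windows, but by less than their standard deviation, and the need to exceed that spread was added after the value was seen. Per the labels both genotypes also carried the floxed Hand2 allele, so the Hand2 window decides nothing about it, and linked variants stay open at both loci.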
